A study of Homo sapiens with 6 samples.

How the data were processed

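Poly-T purified RNA of KYSE-30 cells was sequenced on an MGI instrument, per the labels' protocols, in 6 libraries: 3 labelled shNC and 3 labelled shHMGA1. The authors deposited 1 table of gene models with a column per library and their own comparison of the groups. The genome build is hg38, per the submitters' processing notes. The aligner, the quantifier and the gene annotation are not given in the sources used here, and neither is whether counting used strand. Groups and replicate numbers were taken from the sample titles. No sample was left out, and 0 columns of per-sample values went unmatched.

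The values per library are FPKM as deposited by the authors, with 2 decimals. The unit was inferred from the values, since no header names it. Column totals differed between libraries, unlike TPM. Taking 282 to 305 bases off each model's length, a narrow range over the 6 libraries, made value times kilobases sum to the same total in each library, as FPKM would, an offset solved for and so no test of the unit, and single-fragment steps followed the same lengths. The log2 fold change in the authors' table is that of shHMGA1 against shNC, per the file headers and the sign of HMGA1, and the p-value and adjusted p-value columns are the authors' own, per the file headers. The file name says that DESeq2 made the authors' comparison. These columns were used only for the comparison with the authors' deposited table.

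The table held 25058 rows, after 4 lines that continue a broken row were set aside. Of these, 1669 carry a gene name with a number suffix (such as STING1-2) and 1173 are models without a gene name. Such copies may split the reads of 1 gene, so a gene's FPKM can understate its level. Depth was rebuilt from low values of models of moderate length, where 1 fragment gives a fixed step: 18.6 to 22.8 M fragments (M, mega) per library, with 55.7% to 79.9% of the low values within their rounding, or at most 0.15 of a step, of a whole number. That share is too low to recover counts, so no count test was run. The shHMGA1 libraries were the deeper ones. No pair of libraries shared more than 0.6% of exact values among models at 1 FPKM or more, so none was counted as a duplicate.

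A count test had been planned for the case of raw counts; the plan for normalized values was used in its place. Rows at 1 FPKM or more in at least 3 libraries (13289) were tested with limma 3.58.1 in R 4.3.3, with a trend in the variance, on log2(FPKM + 1), group as the only term, and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. A count of 2-fold changes added an absolute log2 fold change of 1 or more. In the rule for named genes FPKM took the place of CPM. The rule named HMGA1, STING1, CGAS, TBK1 and IRF3 always. It added the 10 largest rises and the 10 largest falls among called protein-coding genes with a mean of 5 FPKM or more whose groups did not overlap. It also added up to 2 risers and 2 fallers per list of smallest p with a mean of 1 FPKM or more, and up to 3 members of an enriched term. These choices, and 26 gene lists, were fixed before the data were examined; 24 lists had 2 or more tested members. The lists not tested were mitochondrially encoded genes and endothelial markers. Some genes that the rule names are not reported here.

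Lists were tested with camera (preset correlation 0.01, two-sided) against all other rows tested, with Benjamini-Hochberg adjustment over the lists, again with the correlation estimated from the data, and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. With the estimated correlation 0 lists passed, against 10 with the preset one and 15 with fry. A correlation estimated from 6 libraries is imprecise, so not passing with it does not show that a list did not move. The lists of MHC class I antigen presentation, DNA replication, p53 targets, epithelial-mesenchymal transition, NRF2 targets, fibroblast markers and leukocyte markers passed fry, upwards, and not camera. GO and KEGG terms paired with genes in the deposited table were tested by the hypergeometric test for 10 to 500 tested genes per term, 1 row per gene name, with 10822 annotated genes as background and adjustment over all terms and both directions. Gene positions are from RefSeq on the same build.

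The steps were tested on simulated data for shHMGA1 against shNC: FPKM made from negative binomial counts (dispersion 0.005, a set minimum above the 0.00181 estimated from the shNC libraries) with the shNC means and the rebuilt depths. Of 200 genes drawn to change, 198 were among the 13031 tested. The share recovered was 71.6% of those changed 1.5-fold, 94.0% at 2-fold and 100% at 3-fold, and 12 unchanged genes were called. A list raised in the simulation, the interferon-stimulated genes, passed camera and fry. There 1 other list also passed camera, and some of the raised genes are members of the RNA sensing list as well. With no list raised 0 passed. Simulated genes were drawn independently, so this does not test the preset correlation between genes of a list. When members of 1 term were set as called beside genes drawn at random, that term and others passed, 7 terms in all. Alternatives covered scaling, pseudocounts of 0.1 and 10, no filter, a filter at 5 FPKM, a test against a 1.2-fold change, the replicate number as a block and each library left out in turn. Seed matches were searched in 3' UTRs of GENCODE 29 with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, on 1000 matched gene sets.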

Results

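RNA-seq profiles were compared between KYSE-30 cells with a stable hairpin knockdown of HMGA1 (shHMGA1, 3 libraries) and KYSE-30 cells of the group labelled shNC (3 libraries), taken as the comparison group. KYSE-30 is an established line of esophageal squamous cell carcinoma, and HMGA1 is a small chromatin protein that binds AT-rich DNA. The comparison asks which genes respond to loss of HMGA1, with STING and innate immunity named as the interest of the series. Levels were the deposited FPKM values of 25058 gene models. Depth, rebuilt from the step that a single fragment makes among low FPKM values, was about 18.6 to 19.98 M fragments in the shNC libraries and 20.8 to 22.8 M in the shHMGA1 libraries. The first principal component held 46.7% of the variance and parted the groups. The second held 17.8% and set shHMGA1 replicate 1 (-20.2) apart from the other 5 libraries (-3.92 to 10.4). No label states that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and adjusted p-values are from limma.

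HMGA1 (chromosome 6, 34236873 to 34246231, hg38), the target of the hairpin, measured 839, 873 and 758 FPKM in the shNC libraries and 180, 187 and 207 FPKM in the shHMGA1 libraries. Its mean fell from 823 ± 59.2 to 191 ± 14.1 FPKM (SD, n = 3 per group), to 0.232 of the shNC level, a log2 fold change of -2.10 ± 0.08 (SE; limma adjusted p = 6.12e-06). HMGA2, the other member of the HMGA family, rose from 94.5 ± 4.45 to 124 ± 14.8 FPKM (log2 fold change 0.39 ± 0.09, adjusted p = 0.0226), a call that was lost without any one of shNC replicates 1 and 2 and shHMGA1 replicates 2 and 3 (adjusted p 0.0565 to 0.0802). Of 11 high mobility group genes tested, 4 rose and 1, HMGA1, fell (5 and 1 adjusted over the list alone). With median-of-ratios scaling 1 rose, without shNC replicate 1 or 2 or shHMGA1 replicate 2 or 3 in turn 0 rose, and without shHMGA1 replicate 1 there were 2 rises and 2 falls. The list had a median log2 fold change of 0.20, a mean of -0.04 and a camera adjusted p of 0.755. The mean and the camera test include HMGA1, the target of the hairpin, so they do not describe the other members.

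STING1, the endoplasmic reticulum adaptor that signals cytosolic DNA to TBK1 and IRF3 (chromosome 5, 139475533 to 139482758, hg38), was higher in all 3 shHMGA1 libraries (15.03, 14.93 and 15.54 FPKM) than in any shNC library (11.6, 12.5 and 10.6 FPKM). Its mean rose from 11.6 ± 0.947 to 15.2 ± 0.327 FPKM (SD, n = 3 per group), 1.31-fold, a log2 fold change of 0.37 ± 0.08 (SE; limma adjusted p = 0.0158). The call was lost without shNC replicate 1 (adjusted p = 0.0567) or without shHMGA1 replicate 3 (0.0565), and over the settings that test for any change the adjusted p ranged from 0.00923 to 0.0567. STING1 did not pass a test against a 1.2-fold change (adjusted p = 1). A row named STING1-2, whose relation to the STING1 row is not given in the sources used here and which may share its reads, rose from 10.6 ± 0.892 to 13.7 ± 0.376 FPKM (log2 fold change 0.34 ± 0.08, adjusted p = 0.0223). The partners of STING1 did not pass the test. CGAS, the DNA sensor upstream of STING1, measured 8.39 ± 0.348 and 7.51 ± 0.993 FPKM in shNC and shHMGA1 (adjusted p = 0.341). TBK1, the kinase downstream, measured 6.07 ± 0.455 and 6.80 ± 0.788 FPKM (adjusted p = 0.371), and the transcription factor IRF3 measured 85.2 ± 2.55 and 75.2 ± 5.55 FPKM (adjusted p = 0.107, or 0.0420 without shHMGA1 replicate 1). STING1 was the only one of 20 tested members of the cGAS-STING and IRF signalling list that passed, over all genes tested and adjusted over the list alone. With median-of-ratios scaling IRF1 and IKBKE, named after their values were seen, also passed with negative log2 fold changes (-0.30 and -0.27), so that 1 member rose and 2 fell. With upper-quartile scaling 1 rose and 1, IRF1, fell, and with the length trend taken out 2 rose (STING1 and LRRC8C) and 3 fell (IRF1, IRF3 and IKBKE). The list did not pass camera (adjusted p = 0.825). Its median was 0.04 while its camera direction was down, and the median was -0.02 with median-of-ratios scaling.

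**Figure D1:**
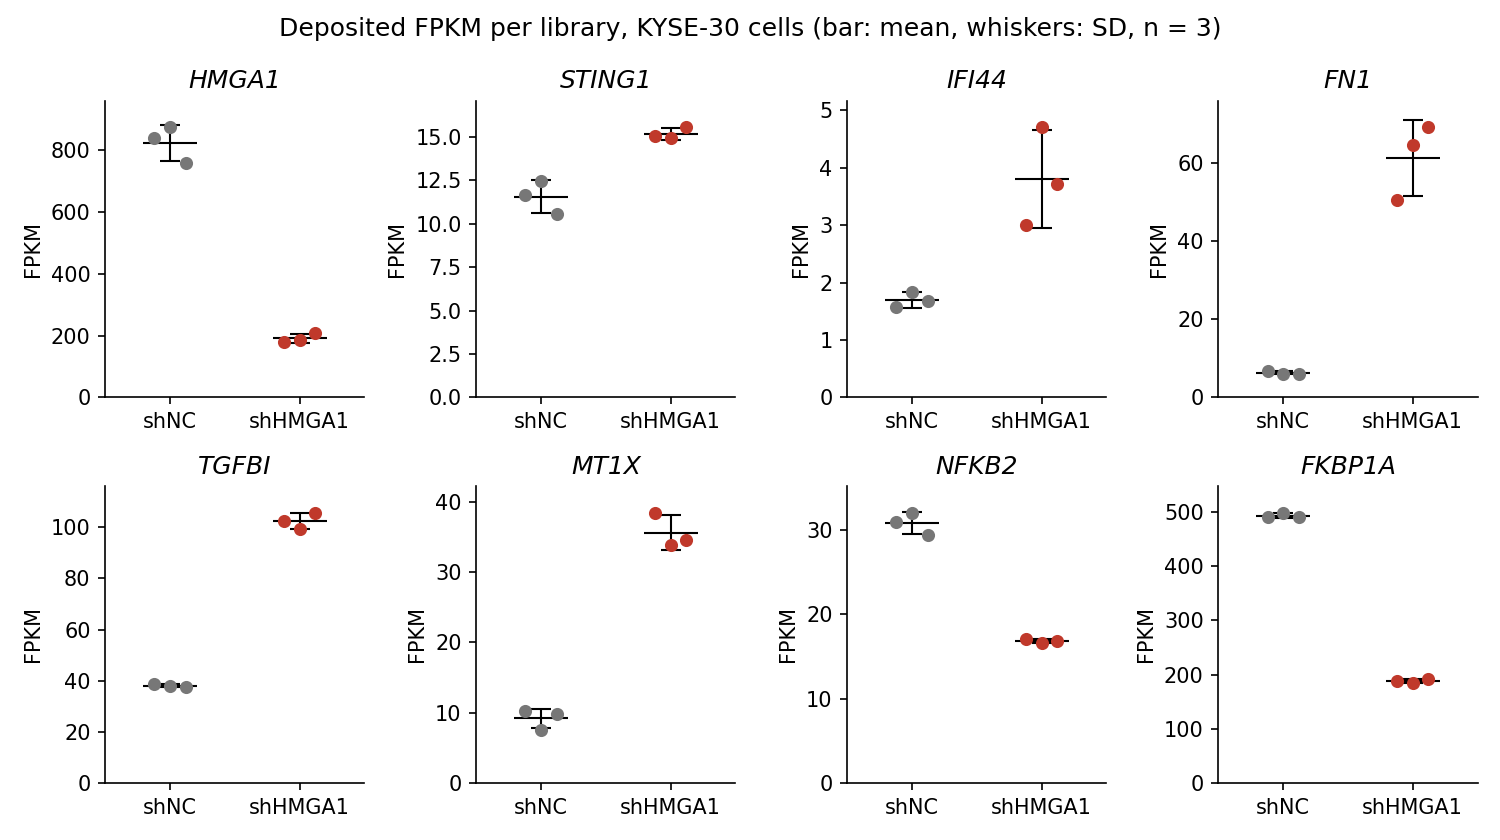
FPKM per library (linear axes from 0) of 8 genes in the 3 shNC and 3 shHMGA1 libraries. Points are libraries, bars are group means and whiskers are SD. HMGA1 lies at 180 to 207 FPKM in shHMGA1 against 758 to 873 in shNC, and in each of the 8 genes the libraries of the groups do not overlap.

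Some genes that type I interferon induces rose. Of 39 tested interferon-stimulated genes, 12 rose and 0 fell (20 and 0 adjusted over the list alone), with a median log2 fold change of 0.28. IFI44 rose from 1.70 ± 0.136 to 3.80 ± 0.854 FPKM and IFI6 from 4.04 ± 1.01 to 8.20 ± 1.02 FPKM (SD, n = 3 per group; adjusted p = 0.00552 and 0.00613). The list passed camera with its preset correlation (adjusted p = 5.94e-05) and fry (0.00538), and did not pass camera with an estimated correlation (adjusted p = 0.246). The count of rises was 7 without shNC replicate 1, 7 without shNC replicate 2, 7 without shHMGA1 replicate 3 and 7 with a filter at 5 FPKM. Without each library in turn, camera with its preset correlation gave an adjusted p of 0.000181 or less.

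More NF-kB target genes fell than rose. Of 23 tested NF-kB target genes 9 fell and 1 rose (9 and 2 adjusted over the list alone), with a median log2 fold change of -0.12. NFKB2, the precursor of the p52 subunit, fell from 30.8 ± 1.32 to 16.8 ± 0.290 FPKM (log2 fold change -0.83 ± 0.06, adjusted p = 0.000211). RELB fell from 13.6 ± 0.681 to 8.74 ± 0.987 FPKM, and the pathway inhibitors TNIP1 and NFKBIA fell from 78.1 ± 4.38 to 53.5 ± 0.650 and from 62.1 ± 2.95 to 49.8 ± 1.44 FPKM. The member that rose was the AP-1 gene JUNB (140 ± 6.19 to 195 ± 10.8 FPKM). The list passed camera (adjusted p = 5.94e-05, or 0.180 with an estimated correlation). The KEGG pathway of NF-kappa B signalling was enriched among fallers, with 10 of 53 genes (adjusted p = 0.0401). The count of falls was 5 without shNC replicate 1, where NFKBIA no longer passed (adjusted p = 0.0555), and 5 without shNC replicate 2. Camera with its preset correlation still passed without each library in turn (adjusted p of 0.000334 or less).

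The other immune lists did not pass camera. Of 11 RNA sensing genes 0 rose and 1 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.413): ADAR, which edits double-stranded RNA, went from 55.6 ± 0.424 to 42.1 ± 3.18 FPKM. Of 15 genes of MHC class I antigen presentation 2 rose and 0 fell, by both adjustments (camera adjusted p = 0.989, direction down against a median of 0.04, which was -0.02 with median-of-ratios scaling), while fry, which does not compare the list with other genes, passed upwards (adjusted p = 0.00538). These were the endoplasmic reticulum folding factors CALR (535 ± 13.6 to 777 ± 31.7 FPKM) and PDIA3 (87.6 ± 2.03 to 110 ± 3.03 FPKM). The list has 22 members in the table, and some were left untested where rows with a number suffix were kept apart. With such copies summed 20 were tested, and again 2 rose and 0 fell (camera adjusted p = 0.889). Of 10 chemokines and cytokines 2 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.554, direction down against a median of 0.02, which was -0.03 with median-of-ratios scaling). CXCL16 rose from 10.7 ± 0.525 to 15.4 ± 1.11 FPKM and TNFSF10 from 1.08 ± 0.185 to 1.91 ± 0.446 FPKM, while LIF fell from 11.8 ± 0.526 to 6.94 ± 0.131 FPKM and IL1A from 2.50 ± 0.531 to 1.41 ± 0.118 FPKM. The calls of TNFSF10 and IL1A were lost without some single libraries (adjusted p up to 0.139 and 0.0718). Of 14 immune checkpoint ligands 1 rose, NECTIN2 (32.6 ± 0.904 to 43.8 ± 2.30 FPKM), and 0 fell, by both adjustments (camera adjusted p = 0.423). Without shHMGA1 replicate 1 there were 2 rises, and with median-of-ratios scaling 1 rise and 1 fall. With copies summed 16 checkpoint ligands were tested, of which 2 rose and 1 fell (camera adjusted p = 0.135).

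**Figure D2:**
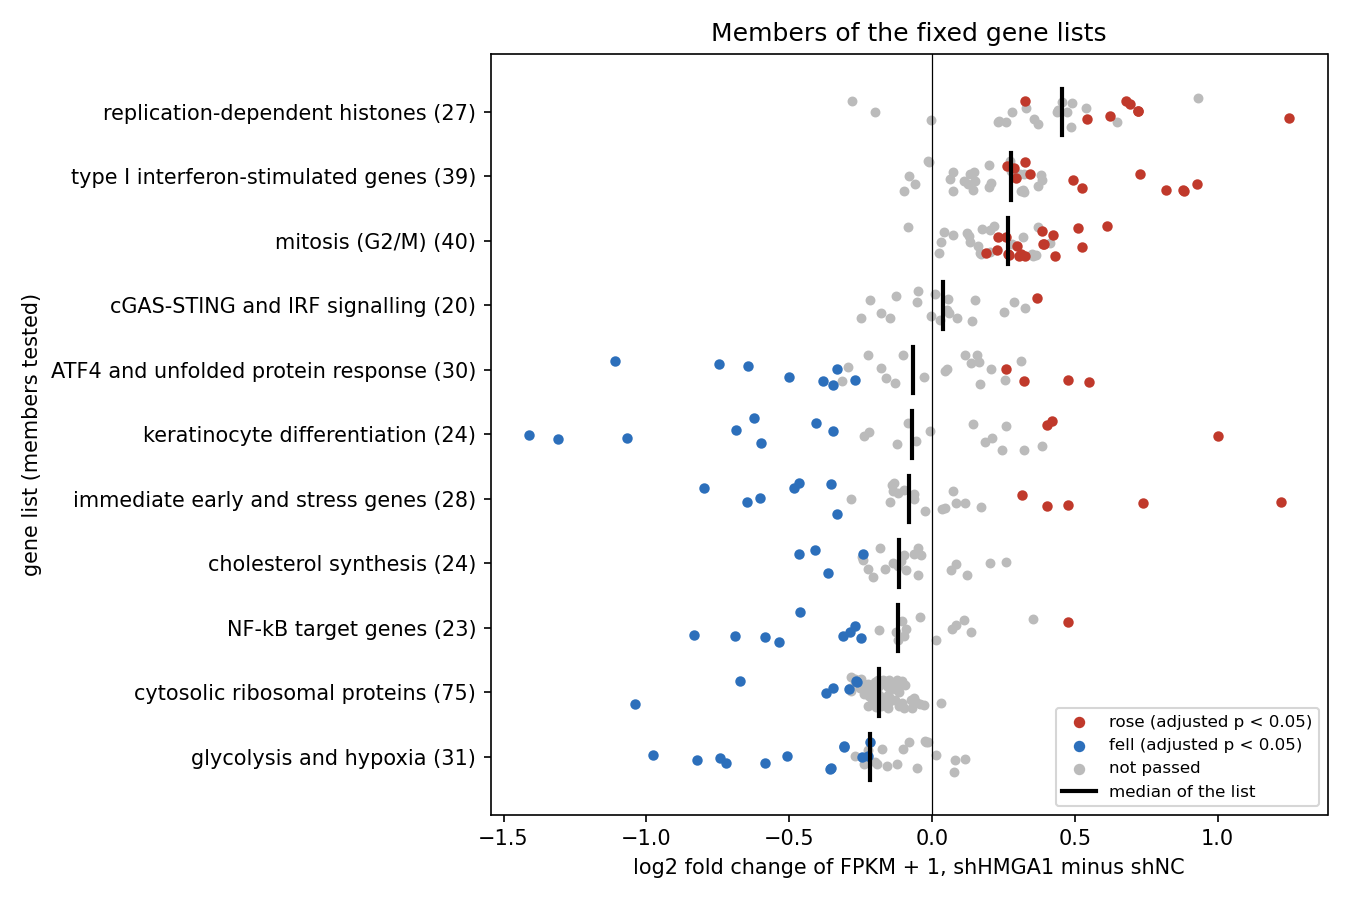
Log2 fold change of FPKM + 1 (shHMGA1 minus shNC, horizontal axis) of each tested member of 11 fixed gene lists, with the number tested in brackets. Points are genes, coloured where the limma adjusted p was under 0.05, and bars are list medians. Medians run from -0.22 for glycolysis and hypoxia to 0.46 for replication-dependent histones, and the median of the cGAS-STING list, 0.04, changes sign with median-of-ratios scaling.

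Over all genes, 2062 of 13289 rows tested changed, 1445 higher and 617 lower in shHMGA1. The share of rises, 70.1%, was 55.8% with median-of-ratios scaling, which called 1122 rows higher and 890 lower. In 36.2% of the rows tested the libraries of the groups did not overlap, against 10% by chance. At least 2-fold changes numbered 73 rises and 20 falls. The count of genes changed was 1011 without shNC replicate 1, 962 without shNC replicate 2 and 1167 without shHMGA1 replicate 3, and 264 rows passed a test against a 1.2-fold change.

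FN1, the extracellular matrix glycoprotein fibronectin (chromosome 2, 215360865 to 215436068), had the largest log2 fold change on the FPKM + 1 scale among the genes named, from 6.31 ± 0.382 to 61.5 ± 9.72 FPKM, 9.74-fold (SD, n = 3 per group; log2 fold change 3.08 ± 0.11, adjusted p = 6.12e-06). TGFBI, a matrix protein induced by TGF-beta, rose from 38.0 ± 0.542 to 103 ± 3.06 FPKM, and PMEPA1, a feedback inhibitor of TGF-beta signalling, from 13 ± 0.0651 to 35.6 ± 2.01 FPKM. The metallothioneins MT1X and MT1E, which bind zinc and copper, rose from 9.18 ± 1.40 to 35.6 ± 2.43 and from 48.6 ± 3.20 to 134 ± 11.8 FPKM. ANKRD1 rose from 12.4 ± 1.33 to 37.9 ± 4.62 FPKM, the metalloproteinase MMP10 from 4.63 ± 0.252 to 13.7 ± 1.16 FPKM, and TXNIP, an inhibitor of thioredoxin and glucose uptake, from 13.8 ± 0.918 to 36.2 ± 0.698 FPKM. ALG5 and the secreted phosphoprotein SPP1 completed the 10 largest rises among genes with a mean of 5 FPKM or more, 2.57-fold and 2.52-fold. After HMGA1, the largest falls at that level were SPRR1A, a cornified envelope precursor (15.4 ± 0.918 to 5.22 ± 1.07 FPKM), FKBP1A, the binding protein of FK506 and rapamycin (493 ± 4.34 to 188 ± 4.49 FPKM), and ICMT, a methyltransferase of prenylated proteins (45.5 ± 1.27 to 17.8 ± 0.721 FPKM). The DNA glycosylase TDG fell from 15.8 ± 1.76 to 5.85 ± 0.806 FPKM, the calcium-binding protein CALB2 from 133 ± 3.59 to 56.7 ± 6.20 FPKM, and the G protein subunit GNA12 from 24.0 ± 1.06 to 9.91 ± 0.490 FPKM. EEF1AKMT4, SLC1A6 and the read-through model RPS10-NUDT3 had log2 fold changes of -1.20 ± 0.08, -1.15 ± 0.09 and -1.27 ± 0.19. Each of these 20 genes had an adjusted p of 0.00393 or less. Members of the metallothionein, SPRR, keratin and histone families are near-identical in sequence, and RPS10-NUDT3 overlaps RPS10, so how their reads were split is uncertain.

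Matrix and adhesion genes led the enriched terms. Of 2967 terms tested on the annotation in the deposited table, 39 were enriched among genes that rose and 15 among genes that fell, and 4 were enriched among genes changed at least 2-fold. The term proteinaceous extracellular matrix held 36 risers of 97 genes (10.4 expected, adjusted p = 3.07e-08), among them FN1, TGFBI and the heparan sulfate proteoglycan GPC4 (14 ± 0.0404 to 33.5 ± 1.05 FPKM). Cell adhesion held 64 of 254 (adjusted p = 8.36e-08), with the integrin subunit ITGB5 rising from 62.9 ± 2.32 to 118 ± 5.23 FPKM. Collagen catabolic process held 12 of 20 (adjusted p = 0.000116), with MMP2 rising from 16.2 ± 0.0985 to 29.9 ± 1.69 FPKM. The KEGG pathways of ECM-receptor interaction (15 of 39, adjusted p = 0.00254) and Hippo signaling (27 of 129, 0.0496) were enriched too, the latter with CCN2 (63.1 ± 1.95 to 116 ± 5.78 FPKM) and TEAD2 (5.92 ± 0.245 to 11 ± 0.795 FPKM). The annotation was taken as deposited and not checked. It places the serine protease gene PRSS23 under G-protein coupled receptor activity, so rows under a wrong term may count in these tests. Of 26 tested genes of epithelial-mesenchymal transition 10 rose and 4 fell (12 and 4 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0693), though it did with a filter at 5 FPKM (0.00745) and without shNC replicate 2 (0.0466). Its camera adjusted p was 0.1235 with no filter, 0.133 with the length trend taken out and 0.0751 to 0.1075 without any one other library. Fry, which does not compare the list with other genes, passed upwards (adjusted p = 0.00276). The list holds epithelial and mesenchymal genes, and both kinds moved both ways. The falls were the mesenchymal genes TNC (17.8 ± 0.986 to 13 ± 1.52 FPKM) and TWIST2 (4.94 ± 0.321 to 3.62 ± 0.297 FPKM) and the epithelial claudins CLDN7 (105 ± 2.50 to 89.0 ± 5.02 FPKM) and CLDN1 (23.8 ± 1.12 to 19.6 ± 1.24 FPKM), and the rises held the epithelial cadherin CDH1 (79.3 ± 0.442 to 101 ± 6.59 FPKM), the last 3 named after their values were seen. The list had 0 falls without shNC replicate 1, 0 without shNC replicate 2, 1 without shNC replicate 3, 2 without shHMGA1 replicate 2 and 1 without shHMGA1 replicate 3. Of markers of other cell types, FBLN1 rose from 12.6 ± 0.347 to 18.3 ± 1.07 FPKM, 1 of 2 fibroblast markers tested (2 adjusted over the list alone; camera adjusted p = 0.0562). With no filter 4 of 11 fibroblast markers rose and 0 fell (camera adjusted p = 0.0293). Of 3 leukocyte markers CSF1R (1.76 ± 0.115 to 4.32 ± 0.319 FPKM) and CORO1A (0.883 ± 0.189 to 1.59 ± 0.232 FPKM) rose and CD68 (3.85 ± 0.0611 to 2.66 ± 0.424 FPKM) fell, by both adjustments (camera adjusted p = 0.413), the CORO1A and CD68 calls being lost without some single libraries (adjusted p up to 0.107 and 0.108). No endothelial marker reached the level needed for testing.

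Squamous differentiation genes moved both ways. Of 24 tested genes of keratinocyte differentiation 3 rose and 8 fell (9 and 10 adjusted over the list alone). SPRR1A fell as given above and EMP1 fell from 80.1 ± 3.36 to 51.7 ± 1.31 FPKM, while the protease KLK6 rose from 7.67 ± 0.323 to 10.5 ± 0.139 FPKM and CNFN from 3.18 ± 1.45 to 7.06 ± 0.367 FPKM. With no filter the CNFN call was lost (limma adjusted p = 0.067), and 1 gene rose and 6 fell of 39. The list's camera adjusted p was 0.0313, and was 0.246 with an estimated correlation, 0.0580 with median-of-ratios scaling, 0.0514 with upper-quartile scaling, 0.0611 with the length trend taken out, where 5 genes rose, 0.0542 without shHMGA1 replicate 1, where 5 genes rose, and 0.0966 without shHMGA1 replicate 2. Of 26 genes of basal squamous identity 2 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.383, median 0.03 or -0.03 with median-of-ratios scaling, mean -0.02). Without shNC replicate 1 or 2 there were 2 falls and without shNC replicate 3 there were 3, and without shHMGA1 replicate 1 there were 5 rises. The lineage factor SOX2 rose from 37.0 ± 2.70 to 53.4 ± 4.54 FPKM and the hemidesmosome gene DST from 25.9 ± 0.942 to 47.9 ± 11.1 FPKM, and the keratins KRT6A and KRT5 fell from 120 ± 5.19 to 64.9 ± 2.00 and from 1.96 ± 0.107 to 0.520 ± 0.167 FPKM. Of 9 simple epithelial markers GATA6 (2.49 ± 0.0819 to 4.08 ± 0.441 FPKM) and FOXA1 (2.49 ± 0.0153 to 3.39 ± 0.0643 FPKM) rose and SOX9 (14.1 ± 0.127 to 10.9 ± 0.579 FPKM) fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.406, or 0.0357 with a filter at 5 FPKM). The FOXA1 and SOX9 calls were lost without some single libraries (adjusted p up to 0.105 and 0.0575).

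Some mitotic genes rose. Of 40 tested, 18 rose and 0 fell (26 and 0 adjusted over the list alone), with a median log2 fold change of 0.27. BIRC5, the survivin gene, rose from 66.9 ± 0.990 to 96.8 ± 6.74 FPKM and the topoisomerase TOP2A from 25.8 ± 0.403 to 40.6 ± 8.43 FPKM. The TOP2A call was lost with no filter (limma adjusted p = 0.0561). The list passed camera (adjusted p = 5.01e-07, or 0.246 with an estimated correlation). The count of rises was 2 without shNC replicate 1, 3 without shNC replicate 2, 9 without shHMGA1 replicate 3, 9 with median-of-ratios scaling and 7 with no filter. The list's camera adjusted p with the preset correlation was 4.0e-06 or less without each library in turn. Of 39 genes of DNA replication 4 rose and 0 fell, by both adjustments, among them the helicase subunit MCM6 (20.2 ± 1.69 to 42.8 ± 3.72 FPKM, log2 fold change 1.05 ± 0.09, adjusted p = 0.000299), and the list did not pass camera (adjusted p = 0.0562), though it did without shHMGA1 replicate 2 (0.0463), with a filter at 5 FPKM (0.0201) and with no filter (0.0115). The DNA replication list's camera adjusted p was 0.271 with median-of-ratios scaling, where 2 genes rose, and 0.138 with upper-quartile scaling, where 3 rose. Without shNC replicate 1 or 2 there were 2 rises (camera adjusted p = 0.104 and 0.0871). Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, were read in libraries made from poly-T purified RNA. Of 27 tested, 8 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 0.000122, or 0.246 with an estimated correlation), with H2BC21 going from 5.94 ± 0.0586 to 10.4 ± 0.0917 and H2BC5 from 17.7 ± 0.543 to 27.9 ± 2.23 FPKM. Without shHMGA1 replicate 1 there were 6 rises and 1 fall (camera adjusted p = 0.026), and without shHMGA1 replicate 2 there were 11 rises.

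Some genes of glycolysis and the hypoxia response fell. Of 31 tested, 13 fell and 0 rose (16 and 0 adjusted over the list alone), with a median log2 fold change of -0.22. NDRG1 fell from 53.3 ± 1.41 to 29.7 ± 1.05 FPKM, the prolyl hydroxylase EGLN3 from 5.54 ± 0.199 to 2.34 ± 0.30 FPKM, hexokinase HK2 from 14.4 ± 0.396 to 8.36 ± 0.428 FPKM and the angiogenic factor VEGFA from 14.9 ± 0.796 to 9.63 ± 0.528 FPKM. The list passed camera (adjusted p = 2.96e-10, or 0.180 with an estimated correlation). The count of falls was 6 without shNC replicate 1, 5 without shNC replicate 2, 8 without shHMGA1 replicate 2, 7 without shHMGA1 replicate 3 and 7 with no filter. Without each library in turn, the list's camera adjusted p with the preset correlation was 1.72e-08 or less. Of 24 cholesterol synthesis genes 4 fell and 0 rose (9 and 1 adjusted over the list alone), among them INSIG1 (31.1 ± 1.03 to 22.3 ± 0.997 FPKM). The camera adjusted p was 9.24e-05 (0.180 with an estimated correlation), and was 0.00051 or less without each library in turn. The count of falls was 7 with median-of-ratios scaling, 9 with upper-quartile scaling, 8 with the length trend taken out, 2 without shNC replicate 1 and 2 without shNC replicate 3. Of 30 genes of ATF4 and the unfolded protein response 8 fell and 4 rose (11 and 7 adjusted over the list alone). The stress effectors DDIT4 and CHAC1 fell from 304 ± 11.9 to 181 ± 9.30 and from 9.78 ± 0.857 to 4.0 ± 0.453 FPKM, and the endoplasmic reticulum chaperones PDIA4 and HSP90B1 rose from 79.5 ± 1.52 to 111 ± 3.71 and from 135 ± 7.88 to 200 ± 30.7 FPKM. That list's camera adjusted p of 0.0313 was 0.246 with an estimated correlation, 0.0515 with median-of-ratios scaling, 0.0790 with a filter at 5 FPKM, 0.0532 with the length trend taken out, 0.0966 without shHMGA1 replicate 2 and 0.0562 without shHMGA1 replicate 3. Without shNC replicate 1 or 2 there were 5 falls and 2 rises, and without shHMGA1 replicate 3 there were 2 rises.

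Few cytosolic ribosomal protein genes passed. Of 75 tested, with a median log2 fold change of -0.19, 7 fell and 0 rose (2 and 0 adjusted over the list alone). RPS10 fell from 2919 ± 236 to 1422 ± 134 FPKM and the RPS26 row fell from 20 ± 0.605 to 12.3 ± 2.69 FPKM. That row may hold only part of the reads of RPS26, which was not tested. The camera adjusted p was 4.27e-15, or 0.331 with an estimated correlation, and fry gave 0.0501, so neither of the latter passed. Without shHMGA1 replicate 1 there were 40 falls, and without any one other library 2 or 3, and with the length trend taken out 29. With suffixed copies summed there were 6 falls. Mitochondrially encoded genes were not analysed here.

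Among immediate early and stress genes 5 rose and 7 fell of 28 (5 and 8 adjusted over the list alone). EGR1 rose from 34.7 ± 0.736 to 82.5 ± 6.67 FPKM (log2 fold change 1.22 ± 0.07, adjusted p = 5.29e-05) and KLF2 from 1.46 ± 0.0929 to 3.10 ± 0.0874 FPKM, while the MAP kinase phosphatases DUSP4 and DUSP5 fell from 50.1 ± 1.3 to 31.7 ± 1.59 and from 36.1 ± 0.572 to 20.4 ± 2.14 FPKM. The list's camera adjusted p of 0.0313 was 0.443 with an estimated correlation, 0.0542 without shHMGA1 replicate 1 and 0.0583 without shHMGA1 replicate 2. Of 25 p53 target genes 4 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.689, median -0.02, mean 0.05): SESN1 and TP53I3 had log2 fold changes of 0.65 ± 0.12 and 0.64 ± 0.12, BAX and GDF15 of -0.33 ± 0.06 and -0.30 ± 0.07. Without shNC replicate 1 or 2 there was 1 fall, and without shNC replicate 2 there were 2 rises. Of 25 NRF2 target genes 4 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.914), with EPHX1 and UGDH at 0.48 ± 0.07 and 0.45 ± 0.09 and SRXN1 and PGD at -0.36 ± 0.06 and -0.24 ± 0.07. Without shNC replicate 1 or 2 there was 1 rise and 1 fall, without shNC replicate 3 there was 1 fall, and without shHMGA1 replicate 3 there were 2 rises and 1 fall. The calls of GDF15, UGDH and PGD were lost without some single libraries (adjusted p up to 0.0861, 0.0545 and 0.172).

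The authors' deposited table gave 2102 rows an adjusted p under 0.05, 978 higher and 1124 lower in shHMGA1, and marked 219 as up and 58 as down at 2-fold or more. Of the rows tested here, 1966 passed in the authors' deposited table, 859 higher and 1107 lower, and 1346 of them were also called here, 0 with the opposite sign. The other 716 rows called here did not pass there. In the authors' deposited table HMGA1 had a log2 fold change of -2.19 and STING1 one of 0.30 with an adjusted p of 0.0931, which did not pass. Other genes called here that did not pass there included CORO1A (adjusted p = 0.203), H2BC5 (0.190), KLK6 (0.173), FOXA1 (0.166), TWIST2 (0.163), TNFSF10 (0.141), CNFN (0.125) and CD68 (0.0583). The median log2 fold change of the tested rows was -0.02 in the authors' deposited table and 0.05 on the FPKM values.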

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

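Tests of summed copies, a length trend taken out, both scalings of the list tests, the 1.2-fold test of single genes, and median-of-ratios scaling of the term and authors' comparisons were chosen after seeing the data. The count of changed genes, 2062, was 264 when tested against a 1.2-fold change and 962 to 2095 without each library in turn, and stayed within 1.5 times under every other setting. The count at 2-fold or more, 93, was 223 with pseudocount 0.1, 12 with pseudocount 10 and 50 with the strict filter on low values, which tests fewer genes. Called list members, 167, ranged from 88 to 207 without each library. Lists past camera, 10, were 0 with the correlation estimated from the data, where the adjusted p of the interferon-stimulated list was 0.246. That list's 12 called members were 7 with the strict filter and 7 to 13 without each library. Enriched terms, 54, were 4 with 2-fold genes alone. HMGA1 kept its call and direction under all settings run. STING1 lost its call at a log2 fold change of 0.37 without shNC replicate 1 and of 0.35 without shHMGA1 replicate 3; the range without each library was 0.31 to 0.42. The direction of the cGAS-STING list turned up with fry (adjusted p = 0.216), which does not compare it with other genes. Where no construction is named, the cause was not tested. STING1 (log2 fold change 0.37) also lost its call when tested against a 1.2-fold change (adjusted p = 1), which 84 of 153 named genes called passed. Under the other settings 134 of the 153 passed throughout, and none of 156 named genes changed direction. With the replicate number as a block, 1590 genes changed, 1452 of them shared, and the epithelial-mesenchymal transition list passed camera (adjusted p = 0.0379). Replicates of the same number did not deviate together (correlations -0.03, -0.13 and -0.13), so the numbers pair nothing. The planned count tests, TMM and library-size scaling were not run, since the values are FPKM. In simulation, 55.3% of 1.5-fold changes were recovered below the median level (9.35 FPKM) and 93.1% above.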

Other observations

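Tests of 3' UTR base composition, of the genes next to HMGA1 and of the excess of rises were chosen after the result was seen.

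Among genes that fell, terms outside the fixed lists were enriched. Negative regulation of apoptotic process held 40 fallers of 345 genes (adjusted p = 0.000453), among them TMBIM6, ASNS and MYC. The KEGG pathway of MAPK signaling held 21 of 175 (adjusted p = 0.0288) and inactivation of MAPK activity 6 of 21 (0.0484), with the phosphatases DUSP4, DUSP5 and DUSP3. KEGG biosynthesis of amino acids held 10 of 54 (adjusted p = 0.0415), with ARG2, PSAT1 and PRPS2, and growth factor activity 11 of 65 (0.0425), with VGF, LIF and VEGFA. Among genes that rose, angiogenesis held 35 of 153 (adjusted p = 0.00401), and endoplasmic reticulum lumen 28 of 113 (0.00541).

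Part of the fall may come from the hairpin's seed acting on other mRNAs, a hypothesis the sequence data allow to be asked although the hairpin sequence is not given in the sources used here. Of all 7-mers of the HMGA1 mRNA, CCTAAGA was the most enriched in 3' UTRs of the fallers, in 78 of 522 against 33.4 expected (z = 8.64; permutation p = 0.001, the smallest that 1000 draws can give), with z = -2.73 in the risers. Of 13066 7-mers absent from the HMGA1 mRNA, 0.0% reached that z, so the enrichment was not shared by 7-mers at large. Expected counts were already matched on UTR length and GC, so this comparison cannot decide on base composition as the source. The excess is 44.6 genes, so it leaves most fallers without such a site, among them NFKB2, while TDG, EEF1AKMT4, GNA12, DUSP4, TNIP1 and ADAR carry 1 or more. SPRR1A and FKBP1A were not among the genes searched. Of genes with the 7-mer 9.05% were called lower, against 4.62% of those without it. Some risers carry it too, among them ITGB5 and FLRT2. The 83 genes with 2 or more sites had a median log2 fold change of -0.0007, against 0.0527 for genes without the 7-mer. Loss of HMGA1 itself stays open for each of the fallers, since 1 hairpin group cannot part it from a seed effect.

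Some genes next to HMGA1 were lower. Of 7 tested genes within 500 kb, 3 fell, 2 rose and 2 did not pass. The fallers were SMIM29 (log2 fold change -0.63), RPS10-NUDT3 (-1.27) and RPS10 (-1.04), and the risers ILRUN and ILRUN-AS1 (0.34 and 1.11). The median, -0.19, was as low in 0.3% of 8360 windows around other genes, but the test followed from seeing these genes, and NUDT3, RPS10-NUDT3 and RPS10 overlap in a chain, so it does not decide for a change along the chromosome. A change along the chromosome stays open. Only 1 faller, SMIM29, at 164 bases from HMGA1, overlaps no other faller, so shared reads may be why RPS10-NUDT3 fell with RPS10. Reads moving between these 2 rows would lower one and raise the other. Both fell, RPS10 from 2919 ± 236 to 1422 ± 134 FPKM and RPS10-NUDT3 from 199 ± 53.5 to 81.1 ± 15.7 FPKM. This argues against sharing between them as the source of the fall of RPS10. No biological explanation was tested.

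More genes rose than fell. The authors' deposited table had the opposite balance over the same tested genes, with 859 higher and 1107 lower (43.7% higher) and a median log2 fold change of -0.02. Median-of-ratios scaling moved the share of rises 71.3% of the way to 50%, but it centres the typical gene at 0 whatever the cause, so scaling and a true excess of rises cannot be told apart by it. Taking out each library's trend with gene length moved it 17.1% of the way, which argues against length as the main source.

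The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. In each case 1 split, the real one, gave the highest count: 2062 changed genes against at most 2 in the others, 93 at 2-fold or more against 2, 167 list members against 0, 10 lists past camera against 6 and 54 enriched terms against 0. Every other split has libraries of both groups on each side. The difference between groups then adds to the spread within its sides and lowers its counts. Even so, 1 to 6 lists passed camera with the preset correlation in those splits.

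Of the 219 genes marked as up in the authors' deposited table, 7 were above 0 in 1 library only.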
